A study of Mus musculus with 8 samples.

How the data were processed

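RNA from 8 mouse samples was hybridised to 8 arrays of 1 slide (Agilent SurePrint G3 Mouse, one colour, Cy3), 1 sample per array. Per the labels' protocols, RNA of brain slices was extracted with QIAzol, RNA of CD4 T cells with TRIzol LS, and both were labelled with a low-input amplification kit. The labels do not say how Treg and nonTreg cells were separated. Per the file headers, all 8 arrays have 1 scan time in common, so no batch could be split; the T cell arrays lie in the first row of the slide and the tissue arrays in the second, and no comparison crosses the rows.

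The scanner files were made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. The processed intensity in the deposited scanner files is a background-subtracted and detrended spot brightness on a linear scale, not normalized between arrays, per the file headers. The authors' deposited series table holds a linear signal, which the values showed to be the processed intensity divided by about the array's 75th percentile: the ratio was constant within each array for 99.89% to 99.97% of probes (tolerance 0.1%), and column medians ran from 0.068 to 0.123. Its scale and centring follow from that ratio, and it was used as an alternative. Each array has 59305 non-control spots for 56605 probes, 300 of which have 10 spots. The median SD between such spots was 0.040 to 0.045 (log2), a technical error only. No spot was saturated. Between 69 and 109 spots per array carried an outlier flag and were left out where other spots of the probe remained.

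Probes were named through their RefSeq accession, without version, against a table of the mouse assembly GRCm38.p6, which was used for names only. Of 56605 probes, 32994 matched 1 symbol, none matched several and 23611 stayed unnamed; 22911 genes had a probe. Signals were averaged over the spots of a probe, log2-transformed and scaled by subtracting the 75th percentile of the array. For the T cell arrays, where most probes were not well above background on the spleen arrays, the percentile was taken over probes well above background on all 4 arrays; for the tissue arrays it was taken over all probes. Each gene was represented by its probe with the highest mean over the 4 arrays of its set. Of 29 further probes of ranked or fixed genes that were measured on both arrays, none went the opposite way at 2-fold, 2 had the other sign and 7 lay more than 2-fold from the probe used.

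A gene entered a comparison when its probe was well above background on at least 1 of the arrays compared. Where the other array was not well above background, the difference is a lower bound, taken against the higher of the dim probe's own value and the lowest value among probes well above background on that array. For 2 of 239 bounds of named genes (Ecel1 and Nr4a3) another probe of the gene was above background on the dim side. Differences of differences used genes above background on all 4 arrays. No test between groups was run, since each group has 1 array; an additive model over the 4 arrays of a set, with its interaction as the error, was not run. Counts are of genes at or over 2-fold.

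Gene lists (28 of pathways and 25 of cell type markers, 623 symbols) were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. Of the list symbols, 1 had no current symbol and 5 had no probe. A list's median difference was set against 10000 random lists of the same size, drawn from compared genes in 20 bins of mean signal; the percentile describes these arrays and is given for lists with at least 5 genes compared. Named genes were the 8 highest and 8 lowest differences measured on both arrays plus the 4 largest bounds each way in the main comparisons (brain Treg against spleen Treg, brain Treg against brain nonTreg, WT ischemia against WT sham, DEREG ischemia against WT ischemia). The other comparisons took 4 and 4 plus 2 and 2 bounds, and the differences of differences 8 and 8. Unnamed loci were passed over, fixed genes were always reported, and each list could add the 3 members with the largest difference and any member that leads another comparison. Some genes named by this rule are not reported here.

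The counting and the list percentile were tested on simulated arrays with 200 genes changed. On a simulated T cell pair of 13388 genes, 97.0% of the 3-fold and 94.0% of the 8-fold changes were recovered, and on a simulated tissue pair of 15806 genes 97.0% and 95.0%. No unchanged gene was counted in either. The only noise simulated was that between spots of the same probe, so this gives no rate of false counts between real samples. Alternatives were normexp background correction (offset 50), quantile normalization, the other probe set for the percentile, the median as scaling point, only genes measured on every array compared, no filter on dim probes, the median over a gene's probes, the deposited series table, and random lists not matched on signal. Normexp was planned on the mean spot intensity but used the median spot and background intensities. Calculations used Python 3.11.15 (numpy 2.4.6, pandas 2.3.3) and R 4.3.3 with limma 3.58.1.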

Results

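Gene expression was measured on 8 one-colour microarrays of mouse RNA, 1 array for each of 8 groups. Groups of the T cell arrays were regulatory T cells (Treg, the CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3) and the other CD4 T cells (nonTreg), both from the ischemic brain of wild type mice at day 14 after stroke and from the spleen of untreated mice. Groups of the tissue arrays were brain slices from the ischemic side of wild type (WT) and DEREG mice at day 14 after stroke or sham surgery. DEREG mice carry a transgene under Foxp3 control that encodes the diphtheria toxin receptor, which makes Treg sensitive to the toxin; the labels used here do not state whether toxin was given. Between 47.6% (spleen nonTreg) and 51.9% (brain Treg) of probes were well above background on the T cell arrays, and between 62.0% and 65.1% on the tissue arrays. With 1 array per group no difference below has a replicate check, so the values describe these libraries, and the number of arrays limits their precision. Differences are log2 values unless given as folds, and "at least" marks a lower bound where the gene's probe was not well above background on the dimmer array.

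Foxp3 was measured first among the T cells, as a check of the labels. Its signal was 7017 in spleen Treg and 9.7, not well above background, in spleen nonTreg, a difference of at least 630-fold. In the brain it was 4717 in Treg and 820.5 in nonTreg, 5.29-fold higher in Treg, so the library labelled brain nonTreg held measurable Foxp3. Il2ra, the high-affinity IL-2 receptor chain, was 88.0-fold higher in Treg than in nonTreg in the spleen and 5.95-fold higher in the brain. Ctla4, an inhibitory receptor of Treg, was 8.55-fold higher in the spleen and 2.17-fold higher in the brain. Htr7, a serotonin receptor gene, was not well above background in any of the 4 T cell libraries, with signals of 12.2 in brain Treg, 9.9 in brain nonTreg, 2.2 in spleen Treg and 2.4 in spleen nonTreg.

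**Figure D1:**
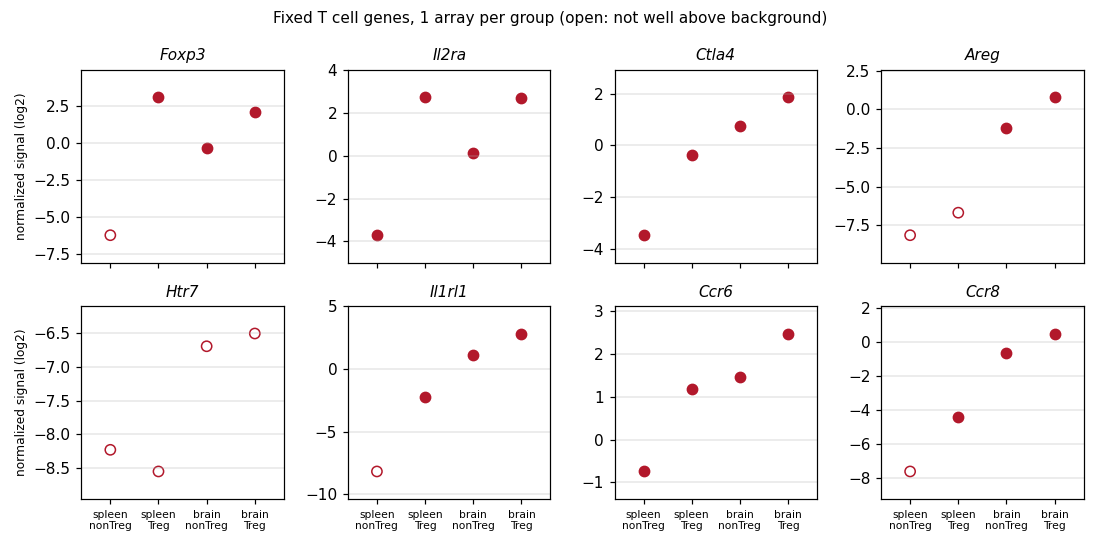
Normalized log2 signal (y axes, 1 scale per gene) of the 8 genes fixed in advance for the T cell arrays, in the 4 libraries (x axes); each point is 1 array, and open points are probes not well above background. Foxp3 was highest in spleen Treg (3.11) and lowest in spleen nonTreg (-6.21), while Areg was well above background in the brain libraries and not in the spleen libraries.

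The first comparison asked how Treg of the ischemic brain differ from Treg of the intact spleen. The brain Treg library held higher transcripts of tissue-type Treg, of cell division and of effector T cells, and lower transcripts of circulating T cells. Areg, encoding the growth factor amphiregulin, was at least 157-fold higher in brain Treg, Il1rl1, encoding the IL-33 receptor ST2, 33.9-fold higher, and Ccr8, a chemokine receptor, 29.6-fold higher. Ccr6 was 2.46-fold higher and Ctla4 4.73-fold higher, whereas Il2ra differed by 1.02-fold and Foxp3 was 2.03-fold lower. Microglia and macrophage transcripts were also much higher in brain Treg, as given below beside the gene groups they accompany. CD8 T and NK cell genes were higher too (median 1.94). Which cells of this library carried each of these transcripts was not tested.

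Of 13779 genes compared, 2372 were at least 2-fold higher in brain Treg and 1619 at least 2-fold lower. The highest measured differences were those of H2-Ab1 (773-fold) and H2-Eb1 (407-fold), both MHC class II genes, Mt1 (281-fold), a metallothionein, Ccl1 (243-fold), a ligand of Ccr8, Trf (178-fold), Apoe (166-fold), Csf1r (158-fold), the receptor for colony stimulating factor 1 on macrophages and microglia, and Fcer1g (154-fold). Another Csf1r probe gave 2.27 on the log2 scale, against 7.30 for the probe used. The largest bounds were for the heat shock genes Hspa1a (at least 12.07) and Hspa1b (at least 2049-fold), Sparc (at least 10.39) and the chemokine gene Ccl4 (at least 9.99). The lowest measured genes were Tmem108 (25.7-fold lower), Susd4 (24.2-fold), Art2b (19.1-fold), Dtx1 (17.4-fold), Gpr83 (17.1-fold), Gprc5b (16.2-fold), Gata1 (16.1-fold) and Sorcs2 (16.1-fold). Slc16a5, Art4, Sostdc1 and Ecel1 were at least 26.7-fold, 25.9-fold, 15.5-fold and 14.9-fold lower, although a further Ecel1 probe, above background in brain Treg, differed by 0.046.

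Among the fixed lists, 17 of 19 tissue Treg genes were at least 2-fold higher in brain Treg, with a median of 2.29, and Il10 (5.91) and Pparg (5.85) followed Areg. This median lay at percentile 100 of 10000 random gene lists of the same size and mean signal. All 15 proliferation genes were higher, with a median of 4.11, including Cdk1 (at least 4.87), Ccnb1 (4.30) and Tpx2 (4.29). Chemokine receptor genes had a median of 3.27, with 12 of 14 higher, among them Cx3cr1 (at least 9.30) and Cxcr6 (5.29). Th1 and cytotoxic genes had a median of 3.42, with 13 of 16 higher, including Gzmb (at least 7.91) and Ccl3 (at least 7.12). Th2 genes (median 3.00, 7 of 7 higher, Il5 at least 3.91) and Th17 genes (median 2.18, 9 of 10 higher, Il17a at least 7.30) were higher as well. Il10 and Il1rl1, with the largest Th2 differences, are also on the tissue Treg list, so the medians of these lists are not independent. Activation and checkpoint genes had a median of 2.02, led by Nr4a2 (5.77), Havcr2 (at least 5.11) and Nr4a3 (4.36). Immediate early and stress genes had a median of 3.37, with Atf3 at least 8.73 higher. Growth and repair factor genes had a median of 1.70, with Csf2 (at least 5.21) and Pdgfb (4.71) after Areg.

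Naive and circulating T cell genes had a median of -1.49, with 8 of 12 at least 2-fold lower, among them Bach2 (-3.44) and Klf3 (-2.54). Conventional T cell genes had a median of -1.17, although Il2 was at least 3.45 higher and Pde3b 3.03 higher. Cholesterol synthesis genes had a median of -0.56 (percentile 1.26). Glycolysis genes had a median of 1.02, with Hk2 at 3.22, Tpi1 at 2.16 and Pgam1 at 1.52, and interferon response genes one of 1.15, with Rsad2 at 3.14, Ifit3 at 2.34 and Ifi44 at 1.95. The Treg core list had a median of 0.91, with 10 genes higher and 4 lower, and members as far apart as Il10, Gpr83 (-4.10) and Tigit (2.29). Neurotransmitter and neuropeptide receptor genes had a median of 0.21 at percentile 74.01, with Adora2a at 1.69, P2rx7 at -1.59 and Adrb1 at least 1.47 higher.

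Markers of other cells differed alongside these groups. Microglia genes had a median of 4.81, with 10 of 12 at least 2-fold higher in brain Treg, including Cx3cr1, Csf1r and Tmem119 (at least 7.27). Macrophage and monocyte genes had a median of 4.53, with 12 of 13 higher, including Adgre1 (at least 6.33) and Ms4a7 (at least 5.88). MHC class II genes (median 4.58, H2-Aa at least 6.98), dendritic cell genes (median 3.58, Cd209a at least 5.11, Itgax at least 5.08), endothelial genes (median 1.72, Cldn5 at least 6.58), pericyte genes (median 2.13, Vtn at least 2.47), meningeal fibroblast genes (median 2.51, Ptgds at least 4.87) and plasma cell genes (median 1.85, Jchain at least 6.34) were higher too. Only 1 dendritic cell gene was above background in both libraries, at -1.08. CD8 T and NK cell genes had a median of 1.94 (Xcl1 5.48, Klrd1 4.72). T cell genes themselves had a median of -0.15, none of the 12 reached 2-fold, and Cd3e was at -0.38. Oligodendrocyte genes (median -0.04), neuron genes (-0.26) and choroid plexus genes (0.31) went both ways. Mal was at least 4.12, Stmn2 at least 2.57, Ttr at least 5.15 and Enpp2 at least 4.34 higher in brain Treg, while Sostdc1 was at least 15.5-fold lower. B cell genes (1.20) and neutrophil genes (0.99) lay at percentiles 94.09 and 88.54. The brain cells came from mice with stroke and the spleen cells from untreated mice. Tissue, stroke and any difference in cell isolation between the organs therefore cannot be told apart here, also for the heat shock and immediate early genes. With normexp background correction 2167 genes, in place of 3991, reached 2-fold. Among genes measured in both libraries 1450 were higher and 1383 lower, so the share of higher genes was 51.2% in place of 59.4%, and with no filter on dim probes 2552 were lower.

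**Figure D2:**
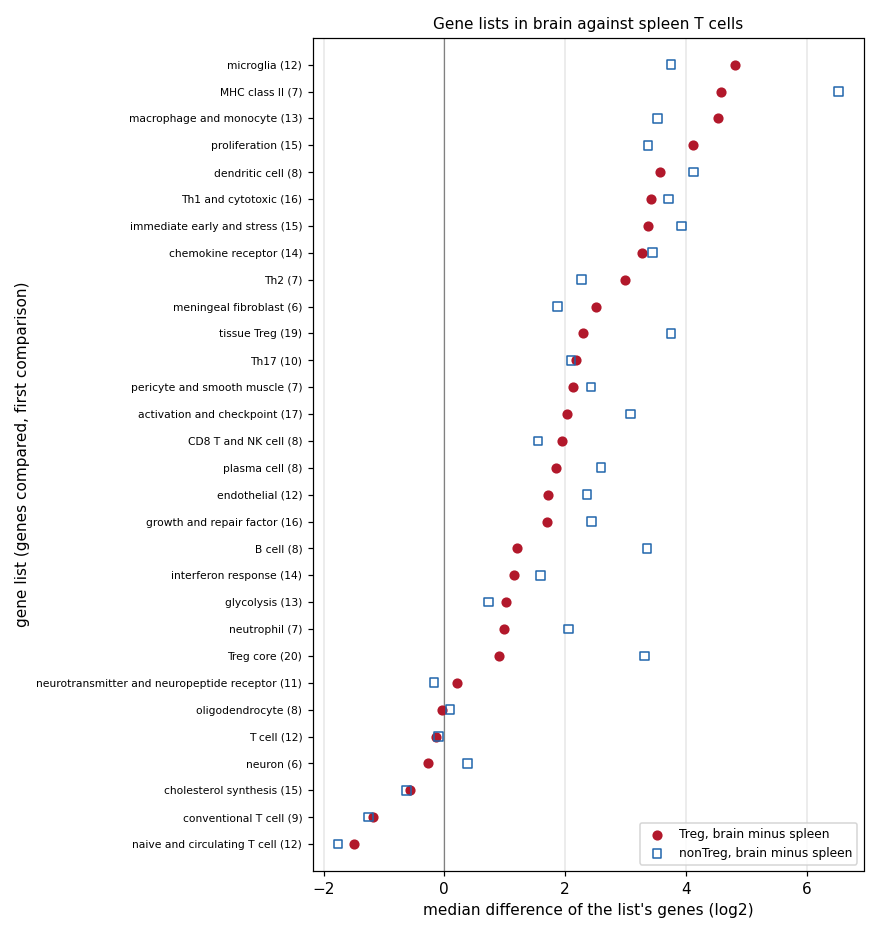
Median log2 difference between brain and spleen (x axis) of each fixed gene list with at least 5 genes compared (y axis, number of genes in parentheses), for Treg (filled circles) and nonTreg (open squares), 1 array per group. Microglia genes were at 4.81 in Treg and 3.75 in nonTreg, and naive T cell genes at -1.49 and -1.76.

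Within the ischemic brain, Treg were higher than nonTreg in Treg core genes, in Areg (3.89-fold) and Il1rl1 (3.21-fold). Treg were lower in Th1 and cytotoxic genes and, with no gene at 2-fold, in interferon response genes. Ccr8 was 2.24-fold and Ccr6 2.03-fold higher. Of 13756 genes, 637 were at least 2-fold higher in Treg and 394 at least 2-fold lower. The highest were Tprg (10.4-fold), Olfr965 (7.81-fold), Sco1 (6.96-fold), Mmp14 (6.48-fold), which encodes a membrane-bound matrix metalloproteinase, Sv2c (6.10-fold), Lrrc32 (5.96-fold), encoding the TGF-beta docking protein GARP, Il2ra (5.95-fold) and Foxp3 (5.29-fold). Another Sco1 probe had the other sign, at -0.59. Nexmif, Cyp11a1, Npsr1 and Myl1 were higher by at least 3.75, 3.75, 3.39 and 3.35. The lowest were the NK receptor gene Klra16 (7.07-fold lower), Il21 (6.53-fold), Lratd1 (5.95-fold), Klra9 (5.89-fold), Cabyr (5.84-fold), Zfp607b (5.59-fold), Serpina9 (5.49-fold) and Klra4 (5.48-fold). Evc2, Tead1, Platr14 and Slc22a13 were at least 17.7-fold, 16.9-fold, 16.6-fold and 14.0-fold lower.

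Treg core genes had a median of 1.21 between the brain libraries, with 12 of 20 at least 2-fold higher and none lower. Tissue Treg genes had a median of 0.75, led by Areg, Klrg1 (1.89) and Il1rl1, and growth and repair factor genes one of 0.55, with Igf1 at 1.49 and Penk, the proenkephalin gene, at 1.29. Proliferation genes had a median of 0.76, with Ccnb1 (1.21), Kif20a (1.17) and Bub1 (1.04) above 2-fold. Th1 and cytotoxic genes had a median of -0.89, with 7 of 16 at least 2-fold lower in Treg, among them Eomes (-2.09), Ifng (-1.91) and Gzmk (-1.84). Conventional T cell genes had a median of -0.67 (Il2 -2.02, Dapl1 -1.85, Cd40lg -1.67), and interferon response genes one of -0.46 with no gene at 2-fold (Oasl2 -0.97). Th2 genes were at 0.55 (Il10 1.39, Il5 1.31) and Th17 genes at -0.57, where Il21 was low and Ccr6 high. Chemokine receptor genes (-0.06), MHC class II genes (-0.09), glycolysis genes (0.14) and cholesterol synthesis genes (0.12) had medians near 0. Microglia genes (median 1.30, 9 of 12 higher) and macrophage genes (median 1.23, 8 of 13 higher) were higher in the Treg library, with Sall1 at 2.17, Tmem119 at 1.66 and Ms4a7 at 1.71. Which cells of the Treg library carried growth factor transcripts such as Igf1 was not tested. CD8 T and NK cell genes (median -1.59, Klre1 -2.38, Klrb1c -2.28), B cell genes (-1.07) and endothelial genes (-0.56, Cdh5 -1.26) were lower. The number of genes at 2-fold was 277 with normexp and 2268 without a filter on dim probes, and 257 genes were lower among those measured in both libraries.

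In the spleen, Treg core genes were higher in Treg than in nonTreg. Lrrc32 was at least 906-fold and Foxp3 at least 630-fold higher in Treg, followed among measured genes by Il2ra (88.0-fold), Coro2a (27.1-fold), Rgs1 (18.8-fold) and Myo1e (17.6-fold). Pdlim4 was 142-fold lower in Treg, Klrd1 41.3-fold, Adamts14 27.4-fold and Nme4 20.4-fold, and App and Atp8b4 were at least 31.4-fold and 31.1-fold lower. Of 12546 genes, 675 were at least 2-fold higher and 406 at least 2-fold lower. Treg core genes had a median of 3.23, with 19 of 20 higher. Activation and checkpoint genes had 10 of 16 members at least 2-fold higher (Il1r2 at least 4.07, Tnfrsf9 2.94, Tnfrsf4 2.82) and tissue Treg genes one of 0.97 (Klrg1 at least 4.09, Penk 3.96). Il1rl1 was at least 15.4-fold, Ccr6 3.81-fold and Ccr8 at least 3.50-fold higher, while Areg was not well above background in either spleen library. CD8 T and NK cell genes (median -1.84) and Th1 and cytotoxic genes (median -0.90, Gzma -2.60) were lower in Treg. The count of 1081 genes at 2-fold was 385 with normexp, 706 among genes measured in both libraries and 2461 with no filter.

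The brain nonTreg library was higher than the spleen nonTreg library in MHC class II, proliferation and Treg genes and lower in naive T cell genes. Microglia, macrophage and B cell genes were higher in it too, so this contrast cannot tell which cells carried the MHC class II transcripts. Whether the Treg transcripts came from Treg cells in this library is weighed further below. Lilrb4a (350-fold), Ccl4 (292-fold), Ly6d (246-fold) and H2-Ab1 (198-fold) were the highest measured genes in brain nonTreg, and Hspa1a and Hspa1b were at least 12.89 and 11.46 higher. Slc16a5 (104-fold lower), Art4 (25.8-fold), Tmie (19.7-fold) and Igfbp4 (18.5-fold) were the lowest, although other probes gave -3.15 for Slc16a5 and -3.18 for Igfbp4, with Tmem108 and Fam205a2 at least 40.4-fold and 23.3-fold lower. Of 13404 genes, 2389 were at least 2-fold higher and 1618 at least 2-fold lower. Treg core genes had a median of 3.31 in this contrast, with 17 of 20 higher in brain nonTreg, including Lrrc32 (at least 7.13), Foxp3 (at least 5.88) and Il10 (at least 5.19). Il2ra was 14.5-fold, Ctla4 18.7-fold and Ccr6 4.61-fold higher, and Areg, Il1rl1 and Ccr8 at least 32.2-fold, 163-fold and 46.3-fold higher. Tissue Treg genes (3.75), proliferation genes (3.37), MHC class II genes (6.53), microglia genes (3.75), macrophage genes (3.53), B cell genes (3.35) and endothelial genes (2.36) were higher, and naive T cell genes were lower (-1.76). With normexp 2119 genes reached 2-fold. Among genes measured in both libraries 1447 were higher and 1334 lower, a share of higher genes of 52.0% in place of 59.6%, and with no filter 2589 were lower. The Treg and nonTreg contrasts share no array: over 13010 genes compared in both, 1741 were at least 2-fold higher in both, where independent lists would share 396.7, and 1026 were lower in both, against 175.0. Across the 11300 genes measured in all libraries, which are not independent replicates, Pearson's r was 0.87. Both contrasts set brain after stroke against untreated spleen, so their agreement can come from anything the brain libraries had in common.

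The brain against spleen difference in Treg minus that in nonTreg was over 2-fold for 688 of 11300 genes, 260 above 0 and 428 below. Pdlim4 (6.74), Nacc2 (4.52), Klrd1 (3.78), Pde3b (3.66), Nme4 (3.60), Adamts14 (3.40), Tmem141 (3.26) and Sgk1 (3.22) had the largest values. Coro2a (-4.36), Rgs1 (-4.31), Il2ra (-3.89), Lilrb4a (-3.71), Ly6d (-3.64), Fhdc1 (-3.58), Cd79b (-3.48) and Map6 (-3.43) had the lowest. Treg core genes had a median of -1.50, with 13 of 16 at or below -1, among them Entpd1 (-3.40) and Socs2 (-3.02). The median of this list between Treg and nonTreg was 3.23 in the spleen and 1.21 in the brain. Ctla4 was at -1.98 and Ccr6 at -0.91. Conventional T cell genes had a median of 1.15. The count was 276 with normexp and 3750 with no filter.

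In the tissue arrays Foxp3 was not well above background in any library, with signals of 2.6 in WT sham, 2.4 in DEREG sham, 2.9 in WT ischemia and 9.8 in DEREG ischemia. These arrays therefore give no check of Treg number by genotype. Stroke in WT mice was accompanied by higher transcripts of phagocytes, reactive astrocytes, complement, interferon response and extracellular matrix, and lower transcripts of neurons, above all of striatal neurons. The tissue lists are named after cell types, but which cells of the slices carried their transcripts was not measured. Gfap, the astrocyte intermediate filament, was 14.2-fold higher in WT ischemia than in WT sham, Lcn2 (lipocalin 2) 138-fold, C3 (complement component 3) 224-fold and Il6 at least 9.02-fold, whereas Cd3e was 1.31-fold higher. Another C3 probe gave 6.15 on the log2 scale.

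Of 16968 genes, 3186 were at least 2-fold higher in WT ischemia and 3123 at least 2-fold lower, and the median of all genes was -0.14. The highest measured genes were Lgals3 (galectin 3, 10.06), Lilrb4a (594-fold), Lyz2 (lysozyme, 550-fold), Ifi204 (341-fold), Ttr (transthyretin, 285-fold), Spp1 (osteopontin, 275-fold), Ccl2 (249-fold) and Ms4a7 (230-fold). Gpnmb, Cd5l, Saa3 and Cst7 were higher by at least 11.10, 10.19, 10.01 and 9.91. Among the lowest were Ido1 (16.1-fold), Syndig1l (15.1-fold), Lrrc10b (14.3-fold), the cannabinoid receptor gene Cnr1 (13.7-fold), Rgs4 (13.5-fold), the dopamine receptor gene Drd2 (13.1-fold) and Scn4b (12.9-fold). C1qtnf9, Olfr651, Pappa2 and Chsy3 were at least 16.7-fold, 10.2-fold, 9.06-fold and 8.94-fold lower. C1qtnf9 was also far lower in DEREG sham than in WT sham, so for it stroke cannot be told apart from a high value of the WT sham array.

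All 13 pan-reactive astrocyte genes were at least 2-fold higher (median 4.04, Cxcl10 6.90, Timp1 6.12), as were 11 of 12 A1 genes (median 4.13, Serping1 4.67) and 10 of 12 A2 genes (median 2.48, Emp1 5.61). General astrocyte genes had a median of 0.40, with Aqp4 at 1.74. Inflammatory cytokine and chemokine genes had a median of 5.48 (Ccl5 7.18), disease-associated microglia genes one of 4.75, complement genes 4.70 (Cfb at least 6.48), interferon response genes 4.63 (Oas1a 6.49, Irf7 6.19), MHC class II genes 5.45 (H2-Aa 5.82) and IL-6 and STAT3 genes 2.86 (Osm at least 5.79, Bcl3 5.07, Socs3 4.15). All 16 extracellular matrix genes were higher (median 3.98, Col3a1 7.51, Col1a1 6.35), as were all 15 proliferation genes (median 2.91, Mki67 5.15). Proteoglycan and glial scar genes had a median of -0.09, with only Cspg4 (1.22) at 2-fold, and axon growth genes one of -0.34, with Atf3 at 5.10 and Gap43 at -1.87. Cholesterol synthesis genes had a median of -1.21, with 12 of 15 at least 2-fold lower (Idi1 -1.92). Glycolysis genes were at -0.64 although Hk2 was 3.95 higher, and immediate early and stress genes at 0.70 (Zfp36 3.73).

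Synapse genes had a median of -1.73, with 14 of 15 at least 2-fold lower (Nlgn1 -2.09, Grin1 -1.99), and all 12 neuron genes were lower (median -1.82, Nefm -2.54). Striatal neuron genes had a median of -3.11 with all 11 lower, excitatory cortical neuron genes one of -1.84 (Tbr1 -2.59), inhibitory neuron genes -1.68 (Gad1 -2.31) and hippocampal neuron genes -0.59. Thalamic and hypothalamic genes were at 0.40, with Prkcd at 3.51 and Slc17a6 at -2.81. Oligodendrocyte genes (-0.20) and their precursor's genes (0.02) had medians near 0, with 3 of the 10 precursor genes at least 2-fold higher. Macrophage and monocyte genes had a median of 4.44, with all 15 higher, and microglia genes 2.65 (Fcrls 4.36). Neutrophil genes had a median of 3.37 (S100a8 6.30), erythroid genes 2.53, plasma cell genes 1.99 (Jchain 4.45) and T cell genes 0.93 (Cd28 4.05). CD8 T and NK cell genes had a median of 2.15, and the only 1 measured on both arrays was at -1.38. Endothelial genes were at 0.54, pericyte genes at 0.88, meningeal fibroblast genes at 3.02, ependymal genes at 2.15 and choroid plexus genes at 3.41, with 12 of 13 choroid plexus genes at least 2-fold higher (Folr1 6.01). B cell (0.72), dendritic cell (0.40) and splenic stroma (-0.19) medians lay at percentiles 85.31, 76.81 and 38.67.

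**Figure D3:**
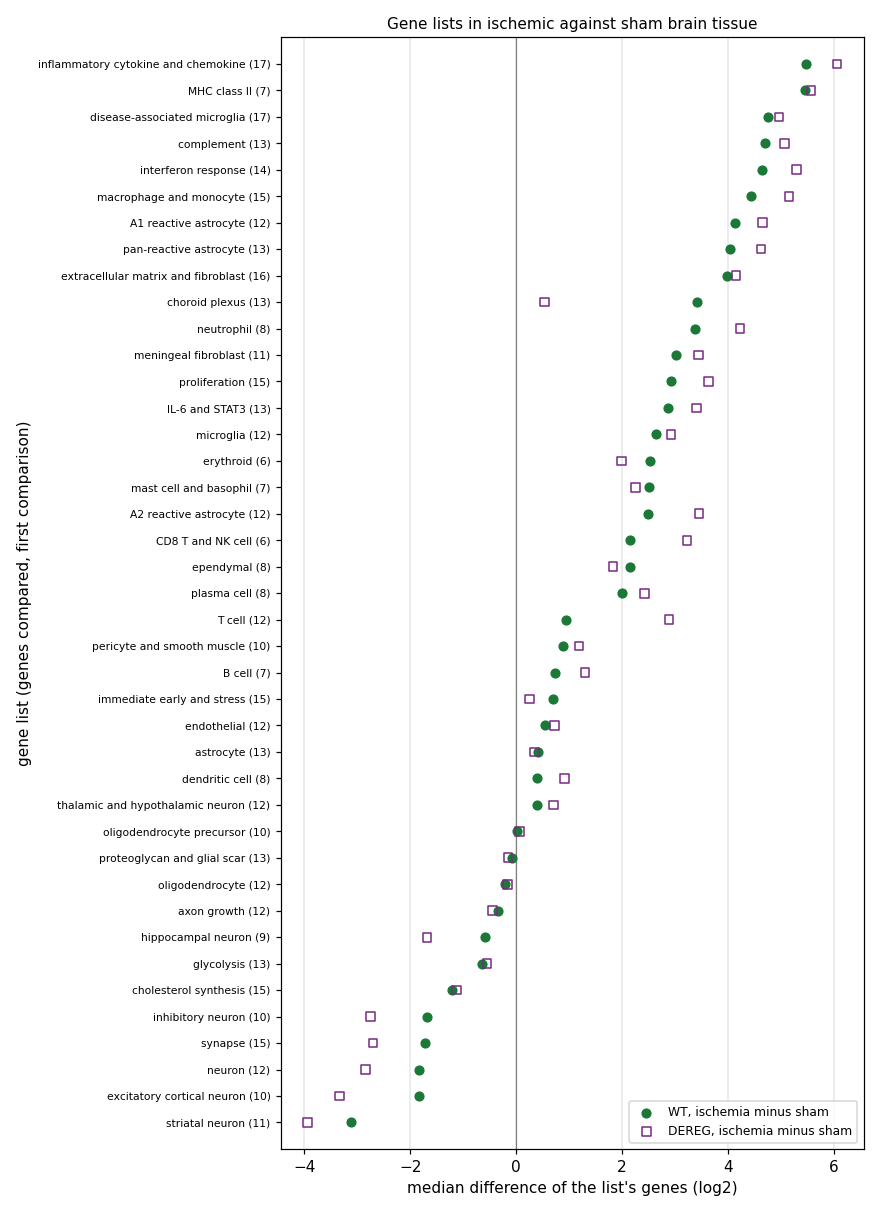
Median log2 difference between ischemia and sham (x axis) of each fixed gene list with at least 5 genes compared (y axis, number of genes in parentheses), in WT (filled circles) and DEREG (open squares) brain tissue, 1 array per group. Choroid plexus genes were at 3.41 in WT and 0.53 in DEREG, and neuron genes at -1.82 and -2.85.

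DEREG tissue after stroke had higher phagocyte and inflammatory transcripts and lower neuron transcripts than DEREG sham tissue. Gpnmb (10.46), Saa3 (10.29), Apoc2 (827-fold) and Lgals3 (785-fold) were the highest measured genes against DEREG sham, and Cd5l and the metalloproteinase gene Mmp3 were at least 813-fold and 758-fold higher. Kcnv1 (65.1-fold lower), Mas1 (37.0-fold), Slc30a3 (32.2-fold) and Nrn1 (30.5-fold) were the lowest, with Adcyap1 and Drd2 at least 22.5-fold and 21.4-fold lower. Gfap was 17.6-fold, C3 339-fold, Lcn2 74.5-fold, Il6 at least 24.5-fold and Cd3e 3.19-fold higher, where other probes gave 7.17 for C3 and 0.83 for Cd3e on the log2 scale. Of 17161 genes, 3837 were at least 2-fold higher and 3799 at least 2-fold lower. Neuron genes had a median of -2.85, synapse genes -2.70, excitatory cortical neuron genes -3.34 (Slc17a7 -4.29), T cell genes 2.89 (Cd3d 5.13) and choroid plexus genes 0.53. The WT and DEREG stroke contrasts share no array: 2971 genes were at least 2-fold higher in both and 2902 lower in both, where independent lists would share 710.4 and 694.6. Across the 15120 genes measured on all 4 arrays Pearson's r was 0.97, and the slope of the DEREG differences on the WT differences was 1.17.

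Comparing the genotypes after stroke, DEREG tissue had higher T cell, cytokine and reactive astrocyte transcripts and lower neuron and choroid plexus transcripts than WT tissue. Cd3e was 2.54-fold, Lcn2 2.69-fold, Il6 2.37-fold, C3 2.35-fold and Gfap 1.63-fold higher in DEREG ischemia. Of 16857 genes, 398 were at least 2-fold higher and 905 at least 2-fold lower. The highest were Cd8b1 (10.5-fold), Avp (vasopressin, 8.86-fold), Cd3g (8.21-fold), Gata3 (7.95-fold), Cd8a (7.47-fold), Gzmb (granzyme B, 7.23-fold), Fgb (fibrinogen beta chain, 7.23-fold) and Ms4a4b (7.21-fold), and the bounds Btg1c, Sit1, Olfr12 and Klra7 (at least 7.17-fold, 6.03-fold, 5.99-fold and 5.31-fold). The lowest were Ttr (53.4-fold), Sostdc1 (10.1-fold), Cox8b (10.1-fold), Clic6 (log2 difference -3.33), Folr1 (9.36-fold), Kcnv1 (8.25-fold), Pcp2 (7.17-fold) and Krt18 (6.84-fold). Defb11, Prr32, Ntf5 and Vmn1r14 were at least 10.3-fold, 7.21-fold, 6.38-fold and 5.17-fold lower.

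T cell genes had a median of 1.64, with 9 of 12 at least 2-fold higher in DEREG ischemia (Cd3d 2.82, Cd2 2.77), and CD8 T and NK cell genes one of 1.34 (Eomes at least 1.78). Inflammatory cytokine and chemokine genes had a median of 1.07, with 9 of 18 higher, including Ccl8 (2.18), Ccl7 (1.92) and Cxcl9 (1.91). Pan-reactive astrocyte genes (median 0.88, 6 of 13 higher, Cxcl10 1.68, Timp1 1.42), interferon response genes (0.87, Ifit1 1.09), MHC class II genes (0.80, H2-Ab1 0.92), IL-6 and STAT3 genes (0.78, Bcl3 1.04), A1 genes (0.72, Iigp1 1.28) and A2 genes (0.69, Ptx3 1.70) had medians above 0 and under 2-fold. Neutrophil genes were at 0.81 (Cxcr2 1.83), macrophage genes at 0.46 (Arg1 1.66), complement genes at 0.51, extracellular matrix genes at 0.34 and microglia genes at 0.22, the last at percentile 83.78. All 10 excitatory cortical neuron genes were at least 2-fold lower (median -1.55, Tbr1 -1.90, Neurod6 -1.85), as were 10 of 15 synapse genes (median -1.18, Grin2a -1.59), 8 of 12 neuron genes (median -1.20) and 7 of 11 striatal neuron genes (median -1.08). Choroid plexus genes had a median of -2.43, with 9 of 13 lower, and erythroid genes one of -0.74 (Hbb-b1 -1.01). Astrocyte (-0.02), oligodendrocyte (0.21), ependymal (-0.03) and proteoglycan (0.03) medians lay near 0. The count of 1303 genes at 2-fold was 576 with normexp and 2180 with no filter.

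**Figure D4:**
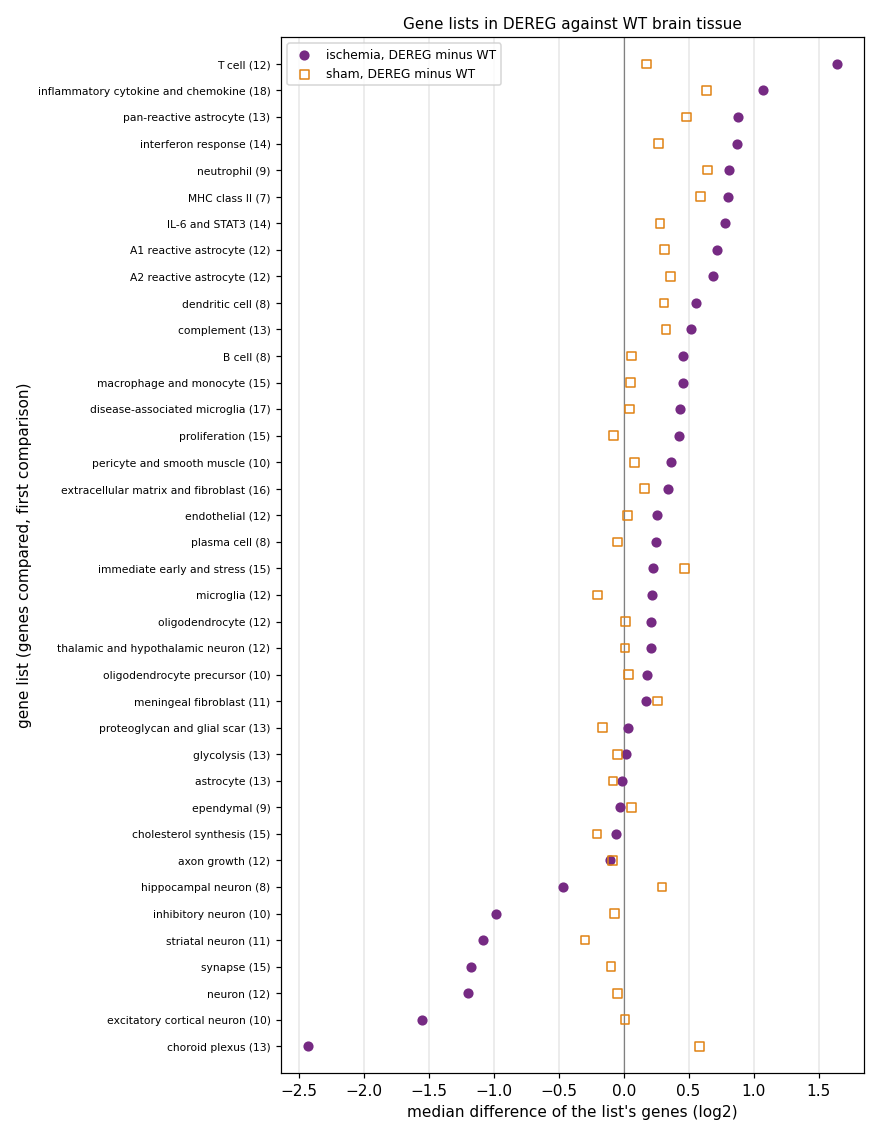
Median log2 difference between DEREG and WT brain tissue (x axis) of each fixed gene list with at least 5 genes compared (y axis, number of genes in parentheses), after ischemia (filled circles) and sham surgery (open squares), 1 array per group. T cell genes were at 1.64 after ischemia and 0.17 after sham surgery, and excitatory cortical neuron genes at -1.55 and 0.01.

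The sham libraries of the genotypes lay closest to each other, with an SD of 0.21 over measured differences. Inflammatory genes were among the few that differed: Lcn2 was 4.99-fold higher in DEREG sham, S100a8 3.72-fold, Ccl2 1.45 and Ccl5 1.44 on the log2 scale. Cytl1 (5.11-fold), Scgb3a1 (4.41-fold) and the bounds Ppm1n (at least 7.39-fold) and Slc36a2 (at least 5.59-fold) were also high. Smim17 (3.39-fold lower), Ghrh (3.11-fold), Sprr2g (2.83-fold) and Prss54 (2.68-fold) were the lowest, although another Ghrh probe was at 0.095, with Syna and C1qtnf9 at least 18.7-fold and 17.9-fold lower. The C1qtnf9 bound rests on the same WT sham signal as its bound in WT ischemia. Gfap was 1.31-fold, C3 1.56-fold and Cd3e 1.04-fold higher, and Il6 was not well above background on either array. Of 16273 genes, 96 were at least 2-fold higher and 73 lower. Inflammatory cytokine and chemokine genes had a median of 0.64, with 5 of 12 at 2-fold, MHC class II genes one of 0.59, pan-reactive astrocyte genes 0.48, immediate early and stress genes 0.47 and choroid plexus genes 0.58, each at percentile 100. Neutrophil markers, S100a8 among them, had a median of 0.64 at percentile 99.9, with 2 of 7 at 2-fold. The count of 169 was 13 with normexp, 62 among genes measured on both arrays and 934 with no filter.

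The stroke difference in DEREG minus that in WT was over 2-fold for 925 of 15120 genes, 137 above 0 and 788 below. Avp (3.98), Il2rb (2.55), Ccl24 (2.49), Ccl8 (2.48), Ltb4r1 (2.38), Cxcr6 (2.23), Mctp2 (2.14) and Sprr2g (2.09) had the largest values. Sprr2g was among the lowest genes in DEREG sham against WT sham, which adds to its value here. Ttr (-7.62), Folr1 (-4.14), Clic6 (-3.86), Sostdc1 (-3.73), Cox8b (-3.72), Kcne2 (-3.05), Kcnv1 (-2.98) and Kl (-2.97) had the lowest. Choroid plexus genes had a median of -3.05, excitatory cortical neuron genes -1.55, neuron genes -1.16, and synapse genes -1.09, all at percentile 0, and T cell genes 1.35 (Lat 1.87) at percentile 100. Interferon response (0.60), IL-6 and STAT3 (0.51) and A1 genes (0.51) were at percentile 100 too, macrophage genes (0.45) at 99.99 and microglia genes (0.37) at 99.95. Pan-reactive astrocyte genes had a median of 0.39 (percentile 99.93), with Lcn2 at -0.89 and Gfap at 0.31, and C3 was at 0.60 and Cd3e at 1.28. Inflammatory cytokine and chemokine genes had a median of 0.36 (percentile 99.2), with 1 of 9 at 2-fold, while MHC class II genes (0.25) and A2 genes (0.25) lay at percentiles 91.9 and 90.7. The cytokine and MHC class II medians between DEREG and WT were 0.64 and 0.59 in the sham arrays. The count was 493 with normexp and 2840 with no filter. With the median in place of the 75th percentile as the scaling point, 206 of the 777 genes at 2-fold lay above 0.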

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

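All tests of explanations in this part were chosen after the results had been seen. The results below were picked out because a gene named by rank or fixed for the report went opposite ways, by at least 2-fold each, in a pair of groups under the same contrast. Among all genes compared in both groups, 21 did so between Treg and nonTreg, 29 between brain and spleen, 7 between ischemia and sham and 6 between DEREG and WT; with 1 array per group none of these differences was tested.

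Between Treg and nonTreg, Fhdc1 was at -2.38 in the brain and 1.20 in the spleen (difference -3.58), and Ly6d at -1.80 and 1.84 (-3.64). Between brain and spleen, Foxp3 was at -1.02 in Treg and at least 5.88 in nonTreg (a difference at or below -6.90). In the same contrast Nacc2 was at 2.09 and -2.43 (4.52), Nme4 at 1.43 and -2.17 (3.60) and Pdlim4 at 3.17 and -3.57 (6.74). Between ischemia and sham, Clic6 was at 1.29 in WT and -2.56 in DEREG (3.86), Cox8b at 2.33 and -1.39 (3.72) and Kl at 1.92 and -1.05 (2.97). Between DEREG and WT, Ttr was at -5.74 after ischemia and 1.88 after sham surgery (-7.62), and Krt18 at -2.77 and at least 1.72 (at or below -4.49).

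Foxp3 and other Treg transcripts in the library labelled brain nonTreg were weighed first. Exchanged labels of the brain libraries would put Foxp3 lower in the library labelled Treg, where it was 2.40 higher. Treg cells in the nonTreg sample, as the source of all Treg transcripts there, would give every strongly Treg-restricted gene about the Foxp3 ratio; of 11 Treg core genes at least 8-fold higher in spleen Treg, 4 (Ctla4, Ebi3, Entpd1 and Socs2) had a brain difference more than 1 below that of Foxp3. Such a mixture stays open for the other 7, among them Lrrc32 and Il2ra. The 7 include Foxp3 itself, which sets the ratio and so was not tested against it. For these 7, expression by brain CD4 T cells that are not Treg cannot be told apart from it, and the median brain difference of the whole Treg core list, 1.21 against 3.23 in the spleen, decides for neither.

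Microglia and macrophage transcripts in the brain T cell libraries were weighed next. The choice among 4 scalings of the arrays is argued against as the source, since the lowest median of both lists together was 4.56. These scalings moved the median of all genes in brain Treg against spleen Treg only between 0.0014 and 0.11, so a large change was not possible. RNA of myeloid cells in the brain samples cannot be told apart from expression by the T cells, since either would give the count seen: 83.3% of the listed genes (20 of 24) were above background in both brain libraries and at least 2-fold above spleen in both, with brain Treg signals of 22917 for Csf1r and 7615 for Cx3cr1, although a sort for CD4 T cells, which the labels do not describe, would remove most such cells. Of the 12 microglia genes 3 are on another list and 4 were above background in spleen Treg; for the 13 macrophage genes these numbers were 3 and 4. Of 23 of these genes measured in both brain libraries, 21 were higher in the Treg library. Unequal amounts of myeloid RNA or unequal expression by the T cells could each give that. The Treg against nonTreg differences of these genes had an SD of 0.65, against 0.48 over all measured genes, which decides for neither. Lists of other cell types were not used in this weighing. Against spleen, endothelial genes were at 1.72 in Treg and 2.36 in nonTreg, and pericyte genes at 2.13 and 2.43. Neuron genes were at -0.26 and 0.38, and oligodendrocyte genes at -0.04 and 0.09.

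Choroid plexus transcripts in the WT ischemia array, which hold Ttr, Clic6 and Kl, were weighed last. More of the ventricle wall than in the DEREG ischemia slice is argued against by ependymal genes, whose median difference between these arrays was -0.030; against WT sham it stays open, since ependymal genes were at 2.15 in WT and 1.83 in DEREG and stroke and slice cannot be told apart. Choroid plexus tissue in the slice would raise the whole list; 69.2% of the genes (9 of 13) were at least 2-fold above both WT sham and DEREG ischemia, and Aqp1, F5, Enpp2 and Kcnj13 were not, which leaves it open. Of the list, 9 genes were above background in WT sham and none is on another list, and the WT ischemia signals were 26647 for Ttr and 14636 for Enpp2. A genotype difference after stroke also stays open and cannot be told apart from uneven sampling with 1 array per group, as the sham arrays already differed by 0.58 as a list median.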

How the results depend on the processing

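The count restricted to genes not above background in WT sham tissue was chosen after seeing the data; the other alternatives were fixed in advance. No paired analysis was run. Array signal over background limits what can be said of dim genes, and the counts of higher and lower genes together moved by over 1.5-fold only under the first 4 settings below. Normexp, whose offset compresses dim signals, gave 2167, 277, 385, 2119 and 276 genes at 2-fold in the T cell comparisons, in the order of the report, and 576, 13 and 493 for DEREG against WT after ischemia, after sham surgery and for the stroke difference between genotypes. With no filter on dim probes the counts were 2268 (brain Treg against nonTreg), 2461 (spleen), 3750 (T cell difference of differences), 2180, 934 and 2840. With only genes measured on every array they were 706 in spleen Treg against nonTreg and 62 in sham DEREG against WT; counted apart, higher genes were then 1450 (brain against spleen Treg) and 1447 (nonTreg) and lower genes 257 (brain Treg against nonTreg). Among genes not above background in WT sham tissue, where far fewer genes were compared, 489, 289, 216, 520 and 77 remained in the T cell comparisons. They made up 49.2% of 994 genes in brain against spleen Treg and 28.8% of 1002 in brain Treg against nonTreg. The share of higher genes fell from 62.4% to 44.9% in spleen Treg against nonTreg, so lower genes were then more numerous. It fell from 61.8% to 52.9% in brain Treg against nonTreg and from 37.8% to 35.1% in the difference of differences. In brain against spleen it rose, from 59.4% to 72.0% in Treg and from 59.6% to 66.2% in nonTreg. Among the scaling alternatives, the share of higher genes among those at 2-fold moved by over 10 percentage points only in the stroke difference between genotypes, from 14.8% to 26.5% with the median as scaling point. That setting moved the median of all genes there from 0.057 to 0.17, and in WT ischemia against sham from -0.14 to -0.31.

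Of 332 list medians with a percentile, 215 lay outside the central 95% of random lists, and 187 to 215 of these did so under each alternative. Directions reversed for 6 list medians: among genes measured on every array, dendritic cell genes in brain against spleen Treg (-1.08) and nonTreg (-0.97) and CD8 T and NK cell genes in WT ischemia against sham (-1.38), where 1 gene each was left, and Th17 genes in spleen Treg against nonTreg (0.15), where 4 were left; with normexp, MHC class II genes in the T cell difference of differences (0.034); and with no filter, growth and repair factor genes there (0.16). Of 815 named gene differences at 2-fold, 661 (normexp) to 815 (no filter) kept 2-fold and direction, except that 600 had a value when bounds were left out. In the T cell difference of differences Gzma became -0.26 with normexp and Ccnb1 -2.47 with the median over its probes. The cause was not tested.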

Other observations

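The neuropeptide genes Avp and Oxt, on the thalamic and hypothalamic list, were 3.15 and 1.37 higher in DEREG than in WT ischemia, while the list's median was 0.21. In the sham arrays Avp was at -0.84. Uneven sampling of the slices cannot be told apart from genotype for these genes either. Htr7, not above background in T cells, was measured in tissue, with signals of 472.9 in WT sham, 443.7 in DEREG sham, 136.0 in WT ischemia and 111.2 in DEREG ischemia, alongside the lower neuron genes.

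Between DEREG and WT, the differences after ischemia and after sham surgery had a Pearson's r of 0.14 across 15120 genes, which are not independent replicates. Of the 187 genes at least 2-fold higher after ischemia and compared in both, 24 were also higher after sham surgery, where independent lists would share 0.88. Of 856 genes lower after ischemia 3 were also lower after sham surgery, against 1.63, and 6 genes went opposite ways by at least 2-fold each. Between Treg and nonTreg, r between brain and spleen was 0.38 across 11300 genes, and 157 genes were at least 2-fold higher in Treg in both, against 17.0 for independent lists.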
